A study of Mus musculus with 4 samples.

How the data were processed

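Liver RNA of CD-1 mice was sequenced by the authors as poly-A-enriched libraries prepared without strand information, per the labels' protocols, from 2 pools of male and 2 pools of female liver. TopHat2, DESeq and edgeR are named with the mouse build mm9 in the submitters' processing notes, without their roles or versions. The deposited gene models name Cufflinks, a transcript assembler, as the source of each line, per the file headers and columns. How transcripts were assembled, filtered and merged, and whether the 4 pools were combined for it, is not given in the sources used here.

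The deposited values are the first and last base of each exon, with a strand, a gene identifier, a transcript identifier and a name. There were 0 columns of values per sample, so sex differences, replicate spread and depth per pool were not analysed here, and the comparison of male with female liver fixed in advance was not made. Precision is therefore limited by the number of genes, and the intervals given cover counting of genes only. The design fixed a count test for values per pool and tests of gene structure for the models, and only the latter apply to exon positions.

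A gene is a gene identifier of the catalogue, and a single-exon gene has 1 exon in each of its transcripts. Spliced length is the sum of exon lengths of the longest transcript. The 4961 numbered loci of the catalogue were checked and equal the genes merged by overlapping spans on either strand. Of the 461 symbols carried by 453 genes, 459 were matched in the RefSeq gene table of GRCm38.p6, 392 by current symbol, 56 by synonym and 11 by gene number. They were of these classes: 352 lncRNA, 60 microRNA, 22 snoRNA, 17 pseudogene and 3 protein-coding, with a few of other kinds. The reference genes were GENCODE M21 on the build GRCm38. Because the builds differ, no coordinate of the reference was converted or printed, and none was used to place a model. Of 412 symbols matched in GENCODE, only 46 have a GRCm38 span that overlaps their mm9 span, a count made only to check that the builds differ. The reference gave names, classes, gene numbers per chromosome, the names of neighbouring genes in its own order, and lengths, spans and exon numbers taken within its own build.

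The tests were fixed before the data were examined, with a threshold of 0.05. Lengths were compared by two-sided permutation tests of medians with 100000 resamples, with intervals from 1000 bootstrap draws over genes. Exon positions were compared within the longest transcript of stranded genes with at least 3 exons by 100000 sign flips, with an interval from the standard error over genes. Isoform numbers were related to exon numbers by Spearman's rho with 100000 permuted pairings. Genes per chromosome were compared by two-sided Fisher's exact tests over 21 chromosomes with Benjamini-Hochberg adjustment, with Wald intervals of the odds ratio. All annotated genes served as the main reference; the plan named annotated genes without saying which, so this choice was made once the annotation was known, and the values with protein-coding and long non-coding genes are given beside it. Clustering was compared with 1000 uniform placements, and orientation and overlap with 10000 permutations of strand within chromosomes, for which the smallest two-sided p is 0.002 and 0.0002. Shares have Wilson 95% intervals.

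The genes named are, by rule, the 3 with the largest genome span, spliced length, exon number in a transcript and transcript number, the cluster with the most genes joined by gaps of 50 kb or less, the 3 closest head-to-head pairs, and each symbol of 5 lists with 44 members that the catalogue names. Older symbols were followed through RefSeq synonyms. Chromosomes, the second clusters and the stretch from Meg3 to Mirg were described after their values were seen. Lincp21 and Trp53cor1, names of the same gene, are separate members of a list, and the gene was counted under the second.

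Alternatives included merged loci, length minimums of 200 and 500 bases, single-exon or multi-exon genes only, other reference genes, other transcripts and exon choices, and other distances. Joining models within 5 kb on either strand, merging overlapping spans in the chromosome counts, leaving out the largest cluster, leaving out genes with a symbol, and the strands of overlapping genes whose exons do not overlap were added after the data were seen. Splice site bases and the nearest protein-coding gene need a genome of the build mm9 and were not analysed here.

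The code was tested in 15 checks that were all met in their final form. Most used simulated data with known answers, and some only compared the models as read with another way of reading them. The overlap on opposite strands, the head-to-head share, the extraction of exon positions, the intervals and the test of multi-exon shares were not simulated. Rank correlation was checked without a planted relation. A first check of the clustering step on a single uniformly placed set of 5506 genes gave a p under the threshold and was then replaced by 40 such sets, of which 1 fell under it. Computations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.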

Results

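Long intergenic non-coding RNAs (lincRNAs) are transcripts that arise between protein-coding genes and carry no evident coding sequence. Poly-A-enriched RNA was sequenced from the livers of untreated CD-1 mice, an outbred laboratory stock, at 8 weeks of age. There were 2 pools of male liver and 2 pools of female liver, each made from the RNA of 6 animals, so that 12 mice of each sex contributed. The data analysed here are a single catalogue of liver lincRNA gene models for the whole series, given as exon positions in the mm9 build. It held 19078 exons in 8588 transcripts of 5506 genes on 21 chromosomes. The models carry exon positions and names but no expression value, so expression in male and female liver and sequencing depth per pool were not analysed here. A model in the catalogue is no measure of how abundant its RNA was, and no value below has a replicate error. Tests across genes describe this catalogue, since genes are not independent replicates of the experiment.

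Which well-studied lincRNAs have a model in the liver catalogue was asked first. Of the 44 members of 5 lists of known non-coding RNAs, 19 carried a model, and all 19 had more than 1 exon. The imprinted list was represented by H19, Meg3, Rian and Mirg, which is 4 of its 8 members. H19, expressed from the maternal allele beside the growth factor gene Igf2, spanned 2615 bases of chromosome 7 (149761437 to 149764051, minus strand) with 2 transcripts of up to 5 exons. Of the 4 members of the X inactivation centre list, the region that controls silencing of one X in female cells, Ftx alone carried a model. It ran over 69818 bases of the X (100749276 to 100819093, minus strand) with 22 transcripts of up to 13 exons, and its longest transcript of 17772 bases was the longest of the 19 members. No model analysed here carried the symbol of any of the 3 members of the nuclear architecture list, Neat1, Malat1 and Miat.

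Among host genes of small RNAs, 7 of 15 members carried a model: Snhg5, Snhg7, Snhg8, Snhg12, Snhg15, Snhg18 and Mir17hg. Snhg5 had 14 transcripts within 1864 bases of chromosome 9, and Snhg8, with a longest transcript of 785 bases on chromosome 3, was the shortest of the 19 members. Snhg12 on chromosome 4 had 15 transcripts and models on both strands. Mir17hg, the host of an oncogenic microRNA cluster, spanned 3203 bases of chromosome 14 (115442749 to 115445951, plus strand) with 3 transcripts.

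Of the 14 other lincRNAs studied in mouse, 7 carried a model. Pvt1, the neighbour of the Myc oncogene, spanned 222366 bases of chromosome 15 (61869542 to 62091907) with 37 transcripts on both strands. Tug1 lay on chromosome 11 (3539397 to 3549057, minus strand) with 8 transcripts and a longest spliced length of 8600 bases. Cyrano, named 1700020I14Rik in the catalogue with the current symbol Oip5os1, is known for driving the decay of a microRNA. It had 9 transcripts and a longest spliced length of 8900 bases on chromosome 2. Norad, which binds Pumilio proteins, had 3 transcripts of up to 4917 bases, also on chromosome 2. Dancr on chromosome 5 reached 1036 bases in 3 exons. Trp53cor1, a target of p53 that lies beside Cdkn1a, and Crnde, which lies between Irx3 and Irx5, each had 1 transcript, of 2 and 7 exons respectively. Over the 19 members the median was 5 exons, 6 transcripts and a longest spliced length of 2937 bases. Symbols were placed by the names in the catalogue, and a model under another name would not have been counted. Of 412 symbols matched in GENCODE, 116 had a longest model of exactly the annotated length, and the sources used here do not say which named models were assembled from liver reads and which were taken from an annotation.

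The imprinted members Meg3, Rian and Mirg lay in a row on chromosome 12 (110779206 to 110987667, mm9), in the domain between the protein-coding genes Dlk1 and Dio3 whose non-coding RNAs are expressed from the maternal allele. Meg3 had 21 transcripts of up to 10 exons over 30734 bases. Rian, a host of small nucleolar RNAs (snoRNAs), had 25 transcripts of up to 22 exons over 57869 bases, and Mirg, a host of microRNAs, had 6 transcripts of up to 9 exons over 15016 bases. Within the 208462 bases from the first base of Meg3 to the last base of Mirg there were 78 transcripts, of which 75 were on the plus strand, 1 was on the minus strand and 2 had no strand. These transcripts carried 27 symbols, namely the 3 lincRNAs, 17 microRNAs and 7 snoRNAs. Of the 24 small RNA symbols, 15 had a gene identifier of their own and 9 were short transcripts under an identifier of Meg3, Rian or Mirg. The 21 gene identifiers of this stretch therefore do not stand for 21 lincRNAs: 4 carried a lincRNA symbol, among them a minus-strand model of Meg3, 15 carried a small RNA symbol only, and 2 had no symbol.

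**Figure D1:**
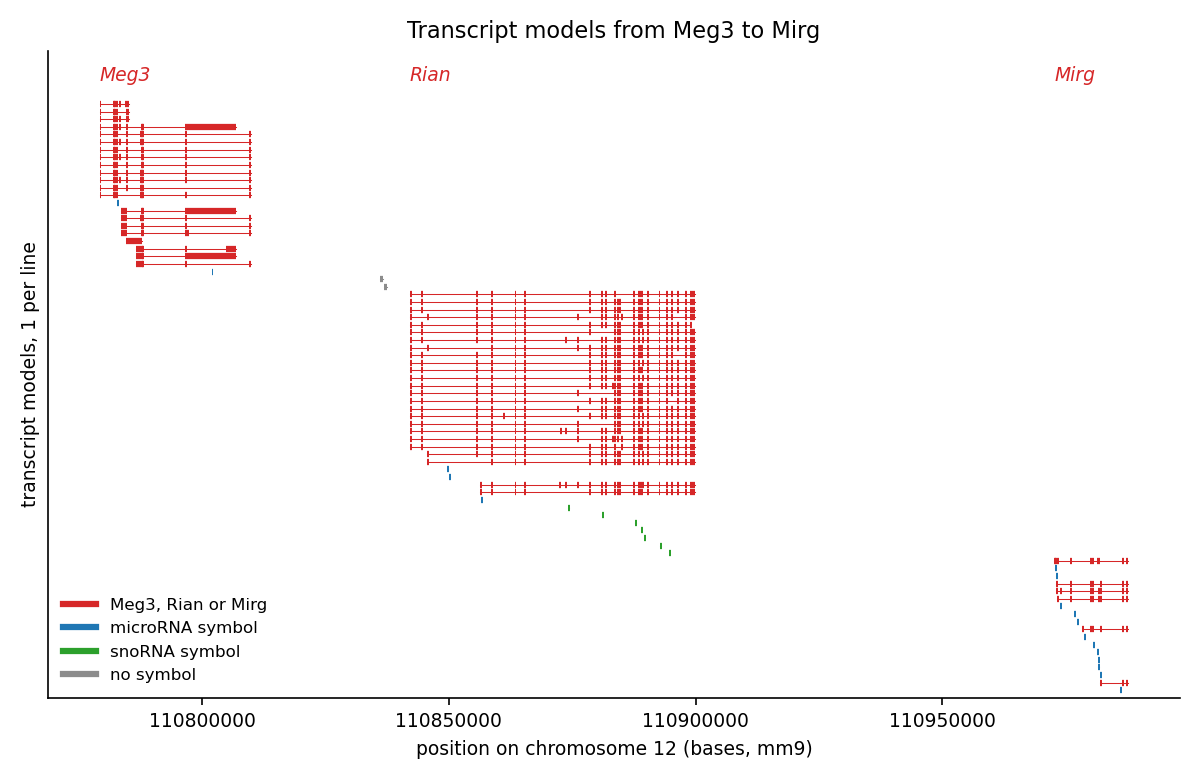
Transcript models of the catalogue from Meg3 to Mirg, 1 per line, ordered by first base. The x axis is the position on chromosome 12 in bases (mm9), thick bars are exons (those under 400 bases drawn 400 bases wide), thin lines are introns, and colour gives the kind of symbol. The 17 microRNA and 7 snoRNA symbols mark short models that lie within the spans of Meg3, Rian and Mirg.

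How single-exon and multi-exon gene models differ was examined next. The catalogue was mostly of single-exon gene models: 4217 of 5506 genes, or 76.6% (95% Wilson interval 75.5 to 77.7), had 1 exon in every transcript. The other 1289 were spliced. A model of 1 exon does not show that the gene has no intron. Some single-exon models carry small RNA symbols, and others may be pieces of longer transcripts, as weighed below. The longest spliced lengths belonged to LiverLincs_chr5_1345_1 and LiverLincs_chr5_1345_2, a pair of unnamed models on opposite strands of the same stretch of chromosome 5 (28358630 to 28386965), with 28336 and 28076 bases, followed by the unnamed LiverLincs_chr1_106 on chromosome 1 (71860185 to 71888434) with 24319 bases. The longest transcript of LiverLincs_chr5_1345_1 covered its whole span and so had no intron. That of LiverLincs_chr5_1345_2 held 28076 of 28223 bases. The libraries did not preserve strand, so the opposite strands of this pair are those given by the authors' models. The genes with the widest genome spans were all spliced: Gm20754 on chromosome 3 covered 528480 bases with 5 exons, A930011G23Rik on chromosome 5 covered 431817 bases with 4 exons, and 2610307P16Rik on chromosome 13 covered 425389 bases with up to 9 exons. The median longest transcript of multi-exon genes was 2275 bases against 1028 bases for single-exon genes, a ratio of 2.21 (95% bootstrap interval 2.05 to 2.41). This difference exceeded all reassignments of genes to the 2 classes (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). Multi-exon genes can also hold transcripts of 1 exon, so the longest transcript of such a gene is not always spliced. With the first transcript listed for each gene, the ratio was 1.73 (95% bootstrap interval 1.59 to 1.84).

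Strand divided the single-exon genes further. All 2529 genes without a strand had 1 exon, with a median length of 1011 bases and quartiles of 735 and 1432 bases. The 1688 single-exon genes with a strand had a median of 1108.5 bases and quartiles of 468 and 2261 bases. Among all genes with a strand, 1448 were on the plus and 1529 on the minus strand. The plus share of 48.6% (95% Wilson interval 46.8 to 50.4) was not distinguishable from a balance of strands (two-sided exact binomial test, p = 0.143). The test treats genes as independent, although 1 cluster on chromosome 6, described below, held 3 plus-strand and 84 minus-strand genes. Without that cluster, 1445 genes were on each strand. The libraries did not preserve strand, so the strand of a gene is that given by the authors' models.

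**Figure D2:**
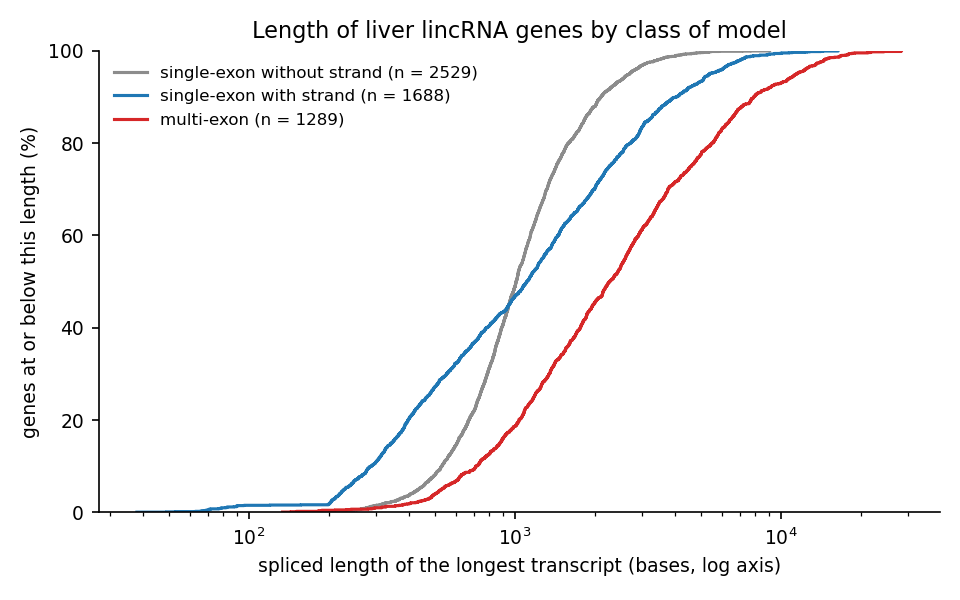
Cumulative share of genes (y axis, percent) by spliced length of the longest transcript (x axis, bases, log axis) for 2529 single-exon genes without strand, 1688 single-exon genes with strand and 1289 multi-exon genes. The multi-exon curve lies to the right, with a median of 2275 bases against 1011 and 1108.5 bases for the single-exon classes.

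The structure of spliced lincRNAs was described by their exons and isoforms. The most exons in a transcript were found in Firre, an X-linked RNA that takes part in nuclear organisation, with 24 exons over 79515 bases (X, 47908921 to 47988435). Rian followed with 22 exons, and the unnamed LiverLincs_chr16_4168_4 on chromosome 16 (24122757 to 24255777, minus strand) had 16. The most transcripts belonged to LiverLincs_chr10_2793_2, named C730027H18Rik, with 43 on chromosome 10 (70625939 to 70645082), to the unnamed LiverLincs_chr4_1254 with 32 on chromosome 4 (139978468 to 139988021), and to the plus-strand gene of Pvt1 with 31.

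Exon length depended on position within the transcript. Medians were taken over 499 stranded genes whose longest transcript had at least 3 exons. They were 227 bases for the first exon, 154 bases for the mean internal exon of a transcript and 993 bases for the last exon. The mean of first and last exon exceeded the mean internal exon of the same transcript 4.0-fold (95% interval 3.57 to 4.47), and did so in 432 of 499 genes (two-sided sign-flip permutation test over genes, p = 1e-05, the smallest possible). The last exon carried most of this: it was 4.93-fold longer than internal exons when taken alone, against 1.40-fold for the first exon.

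Across all 5506 genes, the number of transcripts rose with the number of exons in the longest transcript (Spearman's rho = 0.495, Pearson's r = 0.415, permutation p = 1e-05, adjusted p = 1.33e-05 over 4 relations). The contrast between single-exon and multi-exon genes was part of this relation. Transcripts of a single-exon gene cannot differ in splicing, so part of the rho and p over all genes was fixed by these classes. Of multi-exon genes, 56.6% had more than 1 transcript, against 0.403% of single-exon genes. Within the 1289 multi-exon genes rho was -0.0628 (permutation p = 0.0244, adjusted p = 0.0244) while r was 0.199, so the direction differed between the 2 coefficients. Within the 747 genes with at least 2 transcripts, rho was 0.265 and r was 0.289 (permutation p = 1e-05, adjusted p = 1.33e-05). With all distinct exons of a gene in place of those of its longest transcript, rho over all genes was 0.779, but each added transcript brings exons of its own, so that a higher value is built into this measure.

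Whether any chromosome holds more or fewer lincRNA genes than its share of annotated genes was tested against GENCODE M21. Chromosomes 6 and 7 departed in opposite directions under each of 3 sets of reference genes. Chromosome 6 held 412 lincRNA genes where its share of all 55413 annotated genes gave 311, an odds ratio of 1.35 (95% interval 1.21 to 1.503, adjusted p = 4.54e-07). Against protein-coding and long non-coding genes its odds ratio was 1.51 and 1.32. Chromosome 7 held 276 where 468 were expected, an odds ratio of 0.568 (0.501 to 0.643, adjusted p = 7.49e-21), and gave 0.520 and 0.693 against the other references. In all, 14 of 21 chromosomes passed an adjusted p of 0.05 (two-sided Fisher's exact test with Benjamini-Hochberg adjustment), 9 above and 5 below their share. Of these, 6 kept their direction and passed with every reference, namely chromosomes 6, 7, 12, 15, 16 and Y, the last with limits of build and sex given below. When lincRNA models within 5 kb of each other were counted once, with the reference genes left unjoined, 8 chromosomes passed. Neither chromosome 6 (odds ratio 1.09, adjusted p = 0.290) nor chromosome 12 (1.18, adjusted p = 0.0777) was among them. This depended on the reference: with models joined, 13 chromosomes passed against protein-coding genes, among them chromosomes 6 (1.23, adjusted p = 0.0176) and 12 (1.83, adjusted p = 4.32e-11), and 16 passed against long non-coding genes, without chromosomes 6 (1.07, adjusted p = 0.434) and 12 (1.15, adjusted p = 0.107). With only overlapping spans merged, 11 chromosomes passed against all annotated genes. Among them were chromosomes 6 (1.26, adjusted p = 0.000317) and 12 (1.20, adjusted p = 0.0139). With multi-exon genes only, 3 passed, all below their share, and chromosomes 6 and 12 gave 1.02 (adjusted p = 0.898) and 1.13 (adjusted p = 0.476).

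The sex chromosomes were of separate interest in a comparison of sexes. The X held 114 lincRNA genes, among them Firre and Ftx, and the direction of its departure turned with the reference. Against all annotated genes, 260 were expected (odds ratio 0.427, 95% interval 0.353 to 0.516, adjusted p = 2.72e-22), and against protein-coding genes the odds ratio was 0.468 (0.385 to 0.570, adjusted p = 9.86e-16). Against 13374 annotated long non-coding genes, of which only 183 are on the X, the odds ratio was 1.52 (1.20 to 1.93, adjusted p = 0.00119), that is, more lincRNA genes than that share. The Y held 5 lincRNA genes and lay below its share with each reference, with an odds ratio of 0.0312 against all annotated genes (adjusted p = 7.18e-56), 0.108 against protein-coding genes and 0.0208 against long non-coding genes. The reference counts are those of GRCm38, and whether the Y of mm9 holds the same genes was not checked. The 2 female pools also carry no Y. The low ratio of the Y therefore cannot be read as a property of liver lincRNAs.

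**Figure D3:**
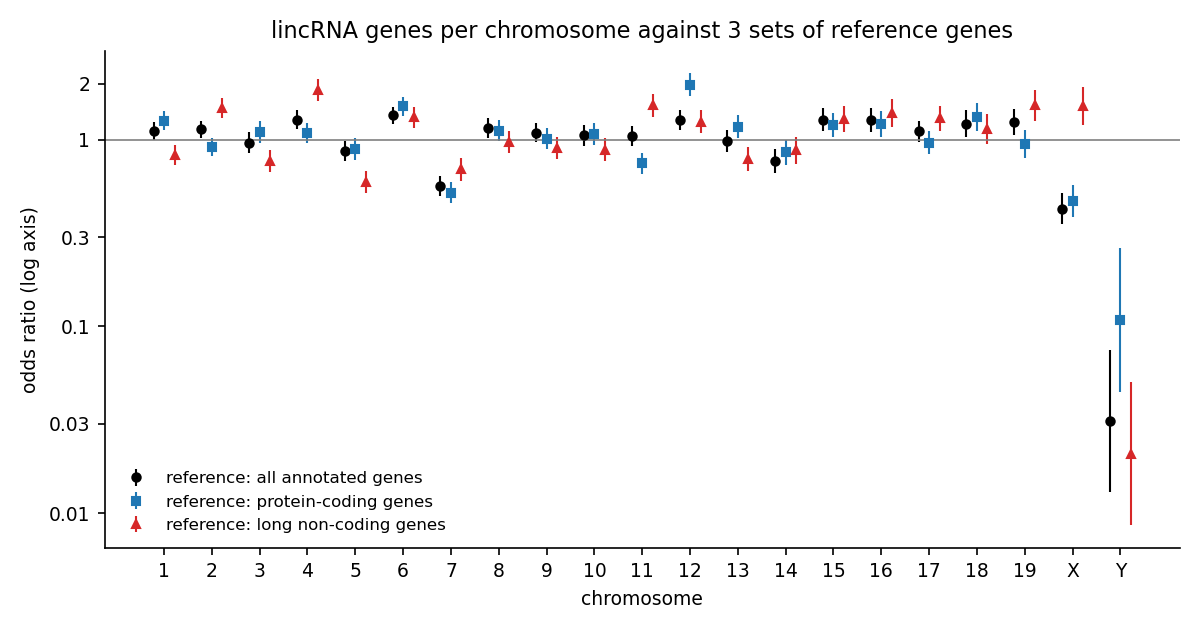
Odds ratio of lincRNA genes per chromosome (y axis, log axis) for chromosomes 1 to 19, X and Y (x axis), against all annotated genes (circles), protein-coding genes (squares) and long non-coding genes (triangles) of GENCODE M21. Bars are 95% intervals, and the X lies at 0.427 and 0.468 with the first 2 references and at 1.52 with the third.

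X-linked genes did not differ detectably in structure from autosomal ones. The median longest transcript was 1198 bases for the 114 genes of the X and 1168 bases for 5387 autosomal genes, a ratio of 1.03 (95% bootstrap interval 0.725 to 1.19, two-sided permutation p = 0.772). Multi-exon genes made up 21.1% (95% Wilson interval 14.6 to 29.4) on the X and 23.5% (22.4 to 24.6) on the autosomes (Fisher's exact test, odds ratio 0.869, p = 0.655). Both adjusted p-values were 0.772. The intervals leave room for a length ratio between 0.725 and 1.19. Within single-exon genes alone, the ratio was 0.837 (permutation p = 0.0380), in the opposite direction, with a 95% bootstrap interval of 0.734 to 1.16 that holds 1. Within multi-exon genes it was 1.42 (0.727 to 1.65, permutation p = 0.166).

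How lincRNA genes lie along the chromosomes was then examined. They lay close together far more often than genes placed at random. The largest cluster, joined by gaps of 50 kb or less, held 88 genes on chromosome 6 (31006392 to 31348773), which is 21.4% of the genes of that chromosome. Of these, 84 were on the minus strand, 84 had a single exon, and the median gap between neighbours was 457 bases. Its named members were 2210408F21Rik on the plus strand and Mkln1os, on the minus strand, which overlaps Mkln1 in GENCODE. The next clusters held 23 genes each, on chromosome 16 (42884391 to 43131984, 22 of 23 on the plus strand) and on chromosome 1 (174563943 to 174744834). Over the genome, the mid points of 45.1% of 5485 neighbouring pairs (95% Wilson interval 43.8 to 46.4) lay within 50 kb, against a mean of 10.8% and a highest value of 12.1% in 1000 uniform placements (two-sided permutation p from these placements = 0.002, the smallest possible). Uniform placement is a crude reference, because genes of all kinds cluster. When models within 5 kb were joined, 20.7% of pairs lay within 50 kb against 7.51% in uniform placements (permutation p = 0.002).

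**Figure D4:**
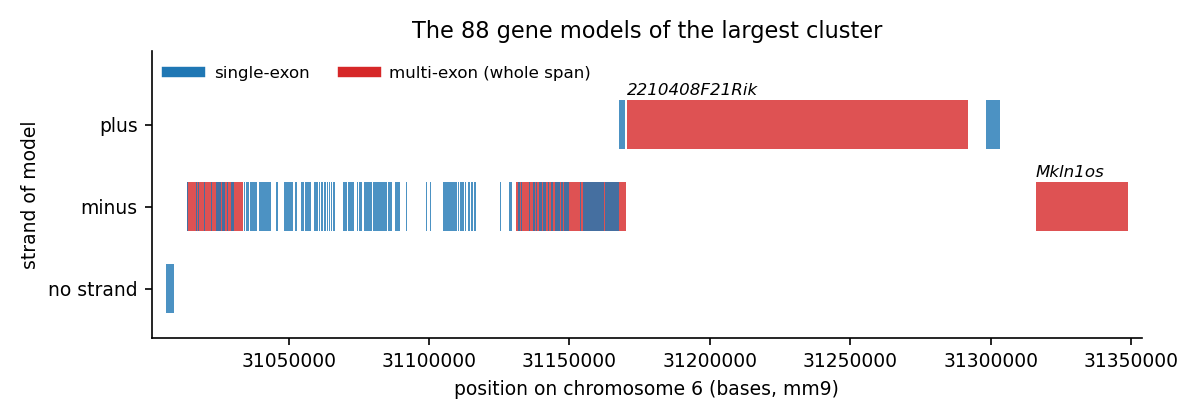
The 88 gene models of the largest cluster on chromosome 6, by position (x axis, bases, mm9) and strand (y axis), with single-exon models in blue and the whole span of multi-exon models in red; models under 400 bases are drawn 400 bases wide. Most lie on the minus strand to the left of 2210408F21Rik.

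Neighbouring lincRNA genes mostly shared a strand. Of 449 neighbouring pairs with strands and a gap of 5 kb or less, 389 (86.6%, 95% Wilson interval 83.2 to 89.5) lay on the same strand, against a mean of 52.7% when strands were shuffled within chromosomes (two-sided permutation p = 0.0002, the smallest possible). Head-to-head pairs, whose modelled start sites are adjacent and whose modelled directions diverge, numbered 37. They made up 8.24% of pairs, against 23.7% with shuffled strands (permutation p = 0.0002). Tail-to-tail pairs, whose modelled ends are adjacent, numbered 23. With so few pairs on opposite strands, a low head-to-head share follows from the same-strand share. It is no separate result and does not show that diverging pairs are avoided. The head-to-head pairs with the smallest gaps were LiverLincs_chr3_868_2 with LiverLincs_chr3_869 on chromosome 3, 39 bases apart (96069297 and 96069337), LiverLincs_chr1_85_5 with LiverLincs_chr1_85_1 on chromosome 1, 67 bases apart (59447848 and 59447916), and LiverLincs_chr6_1664_23 with LiverLincs_chr6_1664_1 in the chromosome 6 cluster, 73 bases apart (31167534 and 31167608). LiverLincs_chr1_85_1 had 2 exons, and each of the other models of these named pairs had 1. The libraries did not preserve strand, so the orientation of these pairs is that given by the authors' models. When single-exon genes were left out before neighbours were paired, there were 62 close pairs of multi-exon genes, not all of them among the 449. Of these, 62.9% shared a strand (95% interval 50.5 to 73.8, permutation p = 0.0520) and 19.4% were head to head (permutation p = 0.365), so neither departure passed the threshold.

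**Figure D5:**
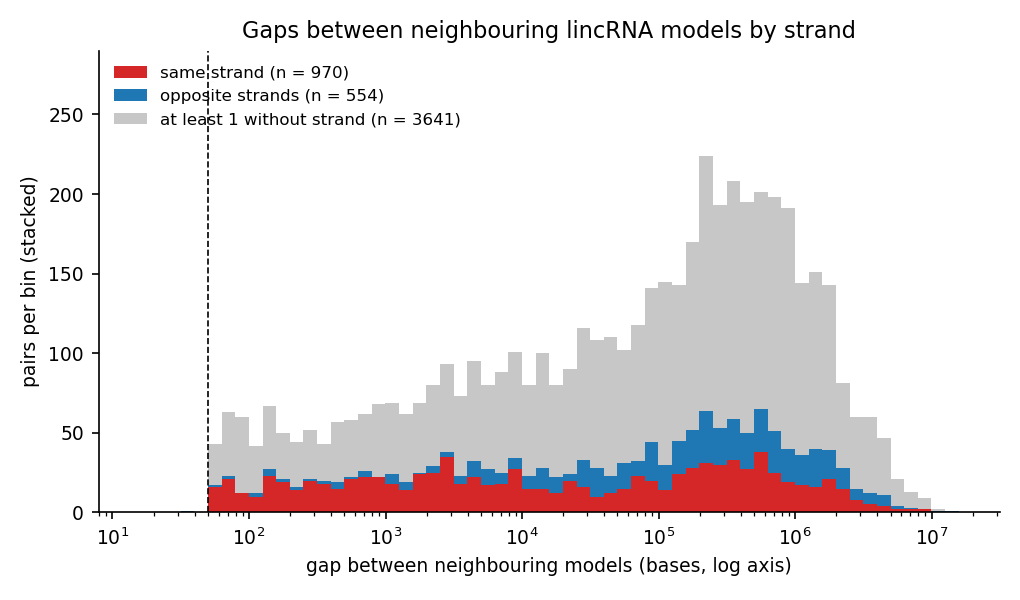
Gaps between neighbouring models that do not overlap (x axis, bases, log axis) as stacked counts of pairs per bin (y axis), coloured by whether both models lie on the same strand, on opposite strands, or at least 1 has no strand. The dashed line marks 50 bases: 1 pair lies closer than this and 166 pairs have gaps of 50 to 99 bases.

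The strands of overlapping genes depended on whether their exons overlapped. Of 428 overlapping pairs of stranded genes, which include the models on both strands at Meg3, Pvt1 and Snhg12, 211 were on opposite strands, against a mean of 206 with shuffled strands (two-sided permutation p = 0.684). Shuffled strands are no fair reference for this total, because no exons of different genes overlapped on the same strand: all 192 pairs with overlapping exons were on opposite strands, a result fixed by the way models were assigned to genes. Of the other 236 pairs, whose spans but not exons overlapped, 19 (8.05%) were on opposite strands, against a mean of 113 shuffled (permutation p = 0.0002, a test chosen after the data were seen). Many short models can lie within the span of the same spliced gene, as at Rian, at Mirg and in the chromosome 6 cluster. Shuffling treats such pairs as independent, which they are not. Among multi-exon genes, 105 of 113 overlapping pairs were on opposite strands, but of the 22 without overlapping exons 14 were (mean 11.1 shuffled, permutation p = 0.316).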

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

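Joining models within 5 kb, merging spans in the chromosome counts, leaving out the largest cluster or genes with a symbol, and overlapping genes without overlapping exons were chosen only after the data were seen. Of 103 alternative values, 83 kept their direction and their side of the threshold, or stayed within 1.5 times a count; 5 of these equal the reported value because their setting changed nothing, and say nothing about stability. The length ratio of multi-exon to single-exon genes stayed between 1.73 and 2.44, and this call, the exon position call and the clustering call passed under each alternative run.

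The X turned direction with long non-coding genes as reference, to an odds ratio of 1.52, and to 1.73 when models within 5 kb were joined as well; the X holds a smaller share of that reference, 1.37% against 4.72% of all annotated genes. For X against autosomal length, single-exon genes alone gave a ratio of 0.837, below 1, and for isoforms against exons, multi-exon genes alone gave rho = -0.0628; the cause was not tested. The count of 14 chromosomes past the threshold became 3 with multi-exon genes only, where fewer genes are tested, and 8 with models within 5 kb joined, but joined models gave 13 against protein-coding genes (10 unjoined) and 16 against long non-coding genes (16 unjoined). With multi-exon genes only, paired anew, 62.9% of close pairs shared a strand and 19.4% were head to head, neither past the threshold with 62 pairs. The other 9 values that lost the threshold were odds ratios above 1: chromosome 4 (1.28 reported) at 1.34 with multi-exon genes only (adjusted p = 0.0536), a larger ratio from fewer genes, and 1.09 against protein-coding genes; chromosome 6 (1.35) at 1.02 to 1.09; and chromosome 12 (1.27) at 1.13 to 1.18. Overlaps on opposite strands, 49.3% in all, were 100% with overlapping exons, as the models' assignment to genes fixes, and 8.05% without; for multi-exon genes they were 92.9% in all and 63.6% without overlapping exons.

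No paired analysis was possible because the models carry no values per pool. For the same reason the alternatives planned for male against female expression (other size factors, no filter, leaving out pools, a replicate block) were not run, nor were those for splice site bases and the nearest protein-coding gene, which need mm9. How far sequencing depth limits the models was not analysed here.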

Other observations

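The tests of gaps between models and the comparisons of microRNA models, of symbols and with GENCODE in this part were chosen only after the data were seen. All 3 patterns weighed here were found in the same catalogue they were tested on. Of 60 microRNA symbols, 19 were carried by a model of at least 200 bases, longer than a microRNA precursor. The 5 with the longest models were Mir365-2 on chromosome 11 (79524808 to 79545407, 13445 bases), Mir345 on chromosome 12 (110074241 to 110087530, 13290 bases), Mir122 on chromosome 18 (65403929 to 65413100, 9159 bases), Mir192 on chromosome 19 (6262652 to 6269774, 7123 bases) and Mirlet7d on chromosome 13 (48627233 to 48641879, 6649 bases). Mir122 is the most abundant microRNA of hepatocytes. Of the 59 microRNA symbols matched in GENCODE, 40 had a longest model of exactly the annotated length. None of the 22 snoRNA symbols was carried by a model of at least 200 bases.

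Of 453 genes with a symbol 79.9% were spliced (95% Wilson interval 76.0 to 83.3), against 18.3% (17.3 to 19.4) of 5053 without. This contrast describes which models carry a name and cannot be read as a property of liver transcripts, since named models can have been taken from an annotation. For 292 lncRNA symbols with a single gene in each source, the longest model was longer than the longest GENCODE transcript in 133, shorter in 90 and equal in 69 (mean log2 ratio 0.15, sign-flip permutation p = 0.00159, adjusted p = 0.00636 over 4 measures). The other 3 measures went the opposite way, each with an adjusted permutation p of 0.00735. Spans were smaller for 124 genes and larger for 100 (mean log2 ratio -0.14), exons were fewer for 55 and more for 36, and transcripts were fewer for 117 and more for 74. The median log2 ratio was 0 for all 4 measures. The extremes of the length ratio were Lockd, with 607 bases against 5662 in GENCODE, and 2900076A07Rik, with 7969 bases against 914.

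Close neighbouring models shared a strand in 86.6% of pairs, and a candidate explanation is that transcripts were assembled as several pieces. Among the 449 close pairs, 93.3% of the 312 pairs of single-exon models shared a strand against 71.7% of the 46 pairs of multi-exon models, a difference of 21.5 percentage points (Fisher's exact test, p = 6.26e-05). Without the largest cluster the difference was 19.7 percentage points (Fisher's exact test, p = 0.000604). This test treats the pairs of a run as independent. Of the 91 pairs with 1 model of each kind, 71.4% shared a strand (95% interval 61.4 to 79.7). The interval of the multi-exon pairs, 57.5 to 82.7, lies above the shuffled mean of 52.7% over all 449 pairs. Single-exon pieces may therefore not account for the whole pattern. Gaps of 50 to 99 bases were 166 times as frequent as gaps of 0 to 49 bases (166 against 1), a test set after the gaps had been seen. An assembler joining anything closer than 50 bases would leave this pattern. It would do so between pieces of a transcript and between separate transcripts alike, so the gaps cannot tell these apart. Strands taken over from a spliced neighbour may add to the pattern, since among single-exon models without a symbol, the 1599 with a strand had a multi-exon model within 5 kb more often than the 2527 without (odds ratio 1.83, Fisher's exact test, p = 7.01e-13). Of 195 pairs with no such neighbour, 94.4% shared a strand (95% interval 90.2 to 96.8, against 52.9% shuffled, permutation p = 0.0002). This argues only against a spliced model within 5 kb as the source of their strands. Spliced models farther off stay open: in the largest cluster, a run of minus-strand single-exon models lies between spliced minus-strand models, many beyond 5 kb. Shuffling also treats the models of such a run as independent. No biological explanation was tested, and true tandem transcripts stay open.

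The X held fewer lincRNA genes than its share of all annotated genes (odds ratio 0.427). More splitting of transcripts on the autosomes is argued against as the whole of this. Joining lincRNA models within 5 kb, with the reference genes left unjoined, gave an odds ratio of 0.484 (Fisher's exact test, adjusted p = 9.79e-13). The choice of reference genes stays open as an explanation, since long non-coding genes as the reference gave 1.52 (adjusted p = 0.00119), although protein-coding genes gave 0.468. Sex of the animals was not tested, because the models are not divided by sex.

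Chromosome 6 held more lincRNA genes than its share (odds ratio 1.35). The choice of reference is argued against for the models as they stand, since the lowest odds ratio with either other reference was 1.32 (adjusted p = 5.26e-05). Splitting of transcripts into several models may account for much of it: joined within 5 kb, the odds ratio was 1.09 (95% interval 0.953 to 1.25, Fisher's exact test, adjusted p = 0.290). With only overlapping spans merged, the odds ratio stayed at 1.26 (Fisher's exact test, adjusted p = 0.000317). Without the 88 genes of the largest cluster the odds ratio was 1.06 (adjusted p = 0.343). Leaving out that cluster lowers the ratio whether its genes are pieces or separate, so this value cannot tell these apart. With joined models the odds ratio was 1.23 against protein-coding genes (adjusted p = 0.0176) and 1.07 against long non-coding genes (adjusted p = 0.434). Once models are joined, the reference thus decides whether chromosome 6 passes. Joining was applied to the lincRNA models and not to the reference genes, and it also merges genes that are truly separate. No biological explanation was tested.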
